A study of Mus musculus with 4 samples.

How the data were processed

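CD4 T cells sorted from pooled tumours of 2 groups of mice were profiled with the 10x 5′ v2 chemistry, which gave 1 RNA library and 1 T cell receptor (TCR) library per group, 4 in all. The RNA values are counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 7.0.0 against mm10 and deposited as filtered matrices, with the version also given per the file headers. The receptor values are contigs with their V and J genes, CDR3 sequences and counts of UMIs and reads, as deposited by the authors. Gene positions were taken from the GRCm38 annotation.

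Barcodes were kept with at least 500 genes and at most 10% mitochondrial UMIs, which left 11933 of 13406 in Tc1 and 8204 of 8449 in Tc9. Before the filters the median barcode had 4725 UMIs in Tc1 and 5179 in Tc9, and 1348 and 220 barcodes had under 500 genes. Scrublet, run per library in scanpy with an expected doublet rate of 0.06, called 0 doublets and so did not work on these libraries, and nothing was removed by it. The alternative without doublet removal was therefore identical and gave no values. Counts were normalised and log-transformed for clustering only, with 2000 variable genes (without TCR and immunoglobulin segment genes), 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1.

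A cluster was taken as T lineage when at least 60% of its cells had a Cd3 UMI, macrophage markers stayed at or under 1000 CPM and its markers gave it no name of another cell type. Clusters with at least 20% of cells with Cd4 and at least 20% with Cd8a or Cd8b1 were clustered again, with the lineage rule applied before this step only. A cluster was CD4 when more of its barcodes had a Cd4 UMI than a Cd8a or Cd8b1 UMI. Names ending in -like were given when at least 3 markers of a fixed list were found in at least 10% of cells and at least 2-fold above the other cells, with at least 1 among the 10 leading genes. The markers were fixed, while the numeric limits of these rules were set with the data in hand. All class names were thus rebuilt here, and the authors' own cell labels were not used.

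Shares have exact Clopper-Pearson 95% intervals, differences of shares combine these by Newcombe's method, and a share of 0 is given with the limit that 3 counts allow, or with the exact upper bound where it is called so. For UMI shares each cell was thinned to 2000 UMIs. Expression was compared as log2 of the ratio of summed UMIs per total (CPM), Tc9 over Tc1, with an exact conditional interval, and a gene at 0 in 1 library entered list medians at the floor of 3 counts. The ratio intervals treat UMIs of the same cell as independent, so they are too narrow for genes with many UMIs in few cells. With 1 library per group there was no test, and a ratio of at least 1.5-fold was counted as higher or lower. The comparison of list medians with 10000 random lists of genes of like expression describes these libraries only. Free RNA in Tc1 was estimated from markers of macrophages and melanoma at 4.54% of the CD4 T cell UMIs, and at 2.57% in Tc9.

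The named genes were fixed by a rule before the data were examined, as were the groups, the gene lists and the alternatives not described as added. The rule took the 12 highest and 12 lowest ratios in CD4 T cells among genes with at least 50 CPM in a library, the 5 highest and 5 lowest in each class with at least 200 cells in both libraries (the Treg-like class), up to 4 members per list with the largest ratios at 10 CPM or more, and 13 genes in every case (Foxp3, Ifng, Il9, Il4, Il17a, Il21, Gzmb, Prf1, Pdcd1, Tcf7, Cd4, Cd8a and Thy1). TCR and immunoglobulin segment genes were left out, and 2 genes are not reported here. It also took the 5 largest clonotypes per library and the 5 TRBV genes with the largest differences. The lists were Treg core and effector, Th1, cytotoxic, Th2, Th9, Th17, Tfh, naive, memory and stem-like, exhaustion and checkpoint, costimulation and activation, type I interferon response, interferon-gamma response, antigen presentation class I, cell cycle S and G2M, glycolysis, nuclear oxidative phosphorylation, hypoxia, cholesterol and lipid, apoptosis and survival, trafficking, dissociation stress, mitochondrial RNA, ribosomal protein, and markers of other cell types.

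A clonotype was an identical pair of TRA and TRB nucleotide CDR3 sequences with V and J genes, among barcodes with exactly 1 productive chain of each, and a clonotype of at least 3 cells was called expanded. Diversity was compared at equal numbers of cells over 100 draws. The alternatives covered cluster resolution, centring per library, filters, thinning, scaling by TMM factors or by the median ratio of genes, cell weighting, a gate on Cd4 UMIs, and the clonotype definition. Added after seeing the data were removal of the barcodes with the shared receptor, of cluster 4, of the naive-like class and of the top Scrublet scores, and subtraction of the expected free RNA, as well as class shares of expanded cells with the Tc9 pairs drawn to the number of Tc1 pairs and a list of the lowest genes without haemoglobin genes and genes with much expected free RNA.

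The ratio intervals were tested on simulated data, where they covered the simulated ratio for 94.966% of 2980 genes in CD4 T cells and for 95.506% of 3182 genes in Treg-like cells. All 79 genes simulated with a 4-fold difference were recovered in both, 63 of 66 at 1.75-fold in Treg-like cells, and 0 of 2780 genes without a difference passed 1.5-fold. The simulated counts were Poisson, the model the intervals assume, without variation between cells, mice or libraries. They check the calculation only and cannot tell how often single libraries differ by 1.5-fold without a treatment effect. The tools were Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.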

Results

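Single-cell RNA and T cell receptor (TCR) sequences were collected from CD4 T cells sorted out of mouse tumours 30 days after inoculation. The B6 mice, which carry the Thy1.2 allele, bore chimeric tumours and had received Thy1.1 Pmel-1 CD8 T cells polarised either as Tc1 or as Tc9 cells, together with an adjuvant. Pmel-1 cells are transgenic CD8 T cells whose receptor recognises the melanocyte antigen gp100, Tc1 cells are CD8 T cells of the interferon-gamma type, and Tc9 cells are CD8 T cells of the interleukin-9 type. Tumours of 3 mice were pooled in each group, and each pool gave 1 RNA library and 1 matching TCR library, called Tc1 and Tc9 here after the transferred cells. There were no replicates, so every interval given is a 95% interval of counting error only (exact for shares, by Clopper-Pearson, and for ratios) and no test between groups was possible. The RNA libraries held 13406 barcodes with 106053410 unique molecular identifiers (UMIs) in Tc1 and 8449 barcodes with 50713493 UMIs in Tc9. After the filters on genes and mitochondrial UMIs, 11933 and 8204 barcodes were kept. The TCR libraries held 8344 productive contigs on 4597 barcodes in Tc1 and 6639 on 4214 barcodes in Tc9.

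The first comparison concerned the cells that the sorted pools held. CD4 T cells made up 20.2% of the kept barcodes in the Tc1 library (2410 cells, 19.5 to 20.9%) and 89.1% in the Tc9 library (7313 cells, 88.4 to 89.8%). Macrophage-like cells, with the complement genes C1qa and C1qb and the lysozyme gene Lyz2, made up 13.1% in Tc1 and 0.207% in Tc9. Dendritic-like cells, with the class II antigen presentation genes H2-Aa and H2-Ab1, made up 9.65% and 0.792%, and 726 of the 1151 Tc1 ones sat in cluster 11, where macrophage markers stood at 13046 CPM against 2825 in the dendritic-like cluster 15. A further 30.5% of the Tc1 and 1.24% of the Tc9 barcodes were outside the T lineage in clusters without a name, and in the larger of these, clusters 5, 9, 10, 18 and 21, macrophage markers stood at 6791 to 23623 CPM, so the macrophage-like class does not hold all barcodes of that kind. Melanoma-like cells, with the pigment genes Pmel, Dct and Mlana, made up 3.13% in Tc1 and 0.0122% (1 barcode) in Tc9. CD8 or other T cells made up 19.1% of the Tc1 and 5.61% of the Tc9 barcodes. All barcodes outside the T lineage came to 60.7% (59.8 to 61.6%) in Tc1 and 5.25% (4.78 to 5.76%) in Tc9. These shares describe the sorted and captured pools and not the tumours. Cell types were rebuilt from clusters and fixed markers, and 4 clusters with Cd3 transcripts in most cells were kept out of the T lineage because macrophage genes stood high in them or natural killer genes marked them (6.49% of Tc1 and 1.51% of Tc9 barcodes).

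**Figure D1:**
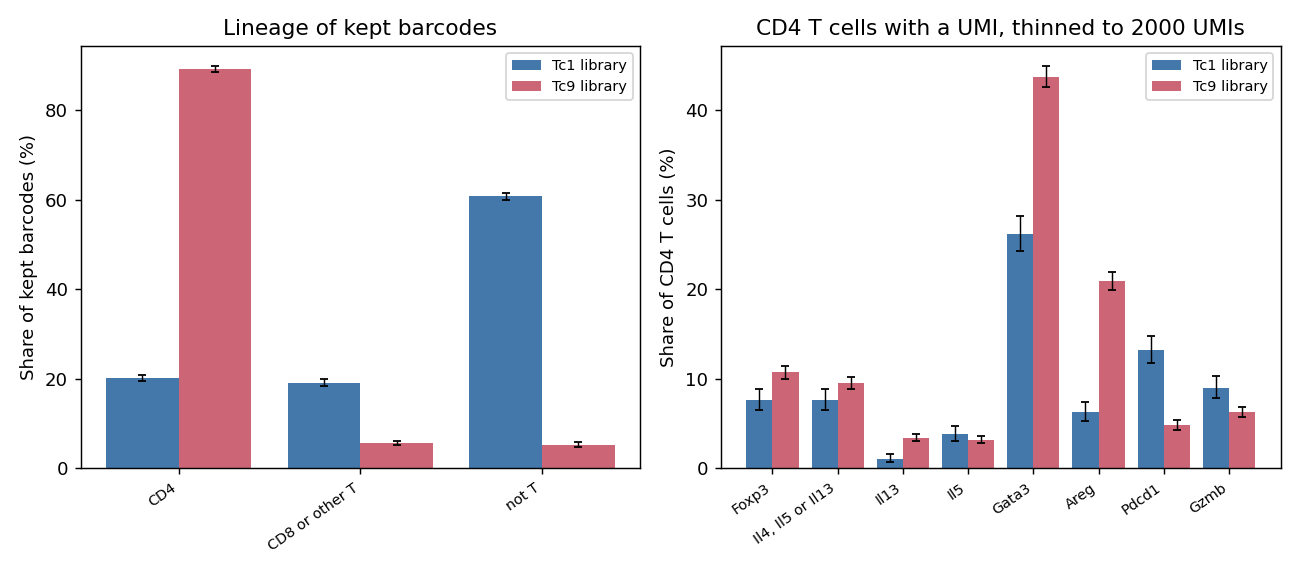
Left, share of kept barcodes (percent) by lineage in each RNA library; right, share of CD4 T cells (percent) with at least 1 UMI of a gene after thinning each cell to 2000 UMIs, with bars for the libraries and error bars for exact 95% binomial intervals. CD4 T cells were 20.2% of the Tc1 and 89.1% of the Tc9 barcodes, and Gata3 and Areg were detected in larger shares of the Tc9 cells.

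The question of which helper and regulatory cells accompanied each transfer was addressed by the classes of CD4 T cells. Th2-like cells, the cluster led by the type 2 cytokine genes Il4, Il5 and Il13 and marked by Gata3, the transcription factor of type 2 helper cells, were 2.20% of the CD4 T cells in Tc1 (53 of 2410, 1.65 to 2.87%) and 12.4% in Tc9 (905 of 7313, 11.6 to 13.2%), a difference of 10.2 percentage points (9.17 to 11.1). Treg-like cells, the cluster led by Foxp3, Il2ra and Ctla4 of regulatory T cells, were 11.5% in Tc1 (278 cells, 10.3 to 12.9%) and 17.6% in Tc9 (1286 cells, 16.7 to 18.5%). Naive or central memory-like cells, with the chemokine receptor gene Ccr7 and the transcription factor gene Lef1, were 18.6% of the Tc1 CD4 T cells (449 cells) and 0.260% of the Tc9 ones (19 cells). Th1 effector-like cells, led by the chemokine gene Ccl5 and the interleukin-12 receptor gene Il12rb2, were 8.13% (196 cells) in Tc1 and 28.4% (2080 cells) in Tc9. Interferon-response-like cells, with Ifit1, Ifit3 and Isg15, were 4.07% in Tc1 and 0.916% in Tc9, and cycling-like cells were 1.58% and 0.998%. Cluster 12.6, with Foxp3 in 95.5% of its cells (27 in Tc1 and 17 in Tc9), was counted as cycling-like and not as Treg-like. No cluster met the marker rule for Th17 or Tfh cells, and Th9 was not among the names that the rule could give.

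The remaining CD4 T cells stayed in the unnamed clusters 0, 4 and 16, of which clusters 0 and 4 belonged mostly to 1 library each and cluster 16 held 3.57% of the Tc1 and 3.61% of the Tc9 CD4 T cells. Cluster 0, led by the costimulatory ligand gene Cd40lg and by Il2, the gene of the T cell growth factor interleukin-2, held 35.2% of the Tc9 and 3.78% of the Tc1 CD4 T cells. Cluster 4 held 46.5% of the Tc1 (1121 cells) and 0.615% of the Tc9 CD4 T cells, and its leading genes were the haemoglobin genes Hbb-bs and Hba-a1, the macrophage genes Lyz2 and Apoe, and the heat shock genes Hspa1a and Hspa1b. Of the naive-like clusters, cluster 6.1 was also led by haemoglobin genes and cluster 6.4 by the heat shock genes Hspb1 and Hspa1a. A cluster held mostly by 1 library may reflect that library and not a cell type, which applies to clusters 0, 1, 4 and 8 and to the naive-like class. The order of the Treg-like shares turned without cluster 4, an alternative chosen after seeing the data, the order of the Th1 effector-like shares turned when only barcodes with at least 1000 genes were clustered, and that of the interferon-response-like shares turned with components centred per library. The Th2-like difference was more than 1.5 times as large with cells thinned before clustering, without barcodes with 2 TRB chains and without the top Scrublet scores. In those clusterings the Th2-like name covered a larger part of the Tc9 cells, so the differences there concern different sets of cells. The Treg-like difference was more than 1.5 times as large with components centred per library and more than 1.5 times smaller with cells thinned before clustering or without the naive-like class. Interferon-response-like and cycling-like differences moved more than 1.5-fold under several alternatives, as did the naive-like and Th1 effector-like differences without cluster 4. At resolution 0.6 the interferon-response-like name covered a far larger part of the Tc1 cells, so its difference there concerns a different set of cells.

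Shares of CD4 T cells with a transcript addressed the same question without cluster names, and each cell was thinned to 2000 UMIs for them (2091 cells in Tc1 and 6886 in Tc9, with 319 and 427 shallower cells left out). Gata3 was detected in 26.2% (24.3 to 28.1%) of the Tc1 and 43.8% (42.6 to 45.0%) of the Tc9 CD4 T cells, and Areg, the gene of the epidermal growth factor receptor ligand amphiregulin, in 6.26% and 20.9%. Il13 was detected in 1.05% and 3.41%. At least 1 of Il4, Il5 and Il13 was detected in 7.65% (6.55 to 8.88%) and 9.51% (8.83 to 10.2%), so that the type 2 cytokine share differed less than the Th2-like cluster did. Of the cells with one of these 3 cytokines before thinning, 68.5% sat in cluster 4 in Tc1, while 49.5% sat in the Th2-like cluster and 36.7% in cluster 0 in Tc9. Foxp3, the lineage transcription factor of regulatory T cells, was detected in 7.60% (6.50 to 8.82%) of the Tc1 and 10.7% (10.0 to 11.5%) of the Tc9 cells. The inhibitory receptor gene Pdcd1 showed the opposite order, with 13.2% in Tc1 and 4.82% in Tc9. Lyz2, which marks macrophages, was detected in 27.4% of the Tc1 and 0.828% of the Tc9 CD4 T cells.

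In barcodes outside the T lineage, thinned to the same depth, Foxp3 was detected in 1.02% (Tc1) and 2.99% (Tc9), Il4, Il5 or Il13 in 0.804% and 4.08%, Gata3 in 3.97% and 15.2%, and Areg in 2.30% and 7.61%. Before thinning, 121 of the 431 such Tc9 barcodes were NK-like, in a cluster with Cd3 in 79.4% of its cells. These barcodes are therefore not a pure measure of background. Without thinning, Foxp3 was detected in 11.3% and 16.1% of the CD4 T cells, whose median depths were 3228 UMIs in Tc1 and 5115 in Tc9. The shares of Gata3, Areg, Il13, Pdcd1, Tbx21, Ifng, Lyz2 and the cytokine triple were chosen after their values were seen. The difference in the Foxp3 share was 3.13 points (1.71 to 4.46), and its direction turned without cluster 4.

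Across all CD4 T cells, the gene with the highest ratio was Il13, the gene of interleukin-13, a cytokine of type 2 responses, at 9.19 CPM (UMIs scaled to the population's total) in Tc1 and 89.0 CPM in Tc9, a log2 ratio of 3.28 (2.97 to 3.60). Il31ra, a chain of the interleukin-31 receptor, followed at 2.29, and Areg stood at 133 and 516 CPM, a log2 ratio of 1.95 (1.87 to 2.03). The other genes among the 12 highest were Gm47283, Peak1, Abcg1, Mpp7, mt-Nd3, Ski, Rpl38, Nfkb1 and Klf10, with log2 ratios from 1.57 to 2.27. The Il13 gene (ENSMUSG00000020383) lies on chromosome 11 from 53631323 to 53634702 and the Areg gene (ENSMUSG00000029378) on chromosome 5 from 91139599 to 91148432 in the GRCm38 reference annotation. Without the barcodes that carried a TRB chain found in both libraries, described further on, an alternative chosen after seeing the data, the log2 ratio of Il13 was 2.56. Cells whose receptor was not recovered could not be removed in this way.

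Of the 12 lowest genes, 11 were haemoglobin or myeloid genes. Hbb-bs, the gene of a beta globin chain of red cells, stood at 4619 CPM in Tc1 and 0.214 CPM in Tc9, Hba-a1 was at least 3196-fold lower in Tc9, where it was not detected, and C1qb, Ccl6, Lyz2, Fcer1g, Tyrobp and Pf4 had log2 ratios from -4.56 to -5.86. The twelfth was Igfbp4, the gene of an insulin-like growth factor binding protein that was among the leading genes of the naive-like clusters, at 171 and 9.09 CPM (-4.23, -4.40 to -4.07). Igfbp4 (ENSMUSG00000017493) lies on chromosome 11 from 99040005 to 99052655, and with classes given equal weight in both libraries its ratio lay within the 1.5-fold size counted as lower. An additional list of the 12 lowest genes with little expected free RNA, without haemoglobin genes, a rule set after seeing the data, held among others the interferon-induced genes Rtp4 (-2.60) and Isg15 (-2.07), the heat shock genes Hspa1a (-2.55) and Hspa1b (-2.20), the chemokine receptor gene Ccr7 (-2.34), the CD8 chain gene Cd8b1 (-2.17), the glycolytic enzyme gene Tpi1 (-2.08), and Actn1, Hist1h2ae and Stk32c. With classes given equal weight, Hspa1a and Hspa1b were higher in Tc9, at 0.16 and 0.29.

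Among the genes followed in every case, Foxp3 had a log2 ratio of 0.14 (0.04 to 0.25), under the 1.5-fold size counted as higher or lower, and its gene (ENSMUSG00000039521) lies on chromosome X from 7579676 to 7595243. Cd4 (-0.09), Thy1 (0.10), Tcf7, a transcription factor of naive and memory T cells (-0.18), and Ifng, the gene of interferon-gamma (-0.44), also lay within that size. Il4 was higher in Tc9 (1.19, 0.98 to 1.40), as was Il17a, from 9 and 181 UMIs (2.19, 1.24 to 3.34). Those Il17a UMIs came from 2 Tc1 and 43 Tc9 cells, so its interval is too narrow. After thinning, Il17a was detected in 0.290% of the Tc9 CD4 T cells, no more than the 1.36% of Tc9 barcodes outside the T lineage, which are not a pure measure of background. Lower in Tc9 were Pdcd1 (-1.82), the granzyme gene Gzmb (-1.12), the perforin gene Prf1 (-2.46) and Cd8a (-2.98). Il21, which helps B cells, gave 0.58 with an interval from -0.58 to 1.97. Il9 had 0 UMIs in Tc1 and 30 in Tc9, all in 1 cell. Gata3 (1.10) and Il5 (0.58) were named after their values were seen, and for Il5 the shares of cells, 3.78% in Tc1 and 3.18% in Tc9, had overlapping intervals and gave no order.

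Type 2 genes were higher as a group in the Tc9 CD4 T cells. The Th2 list had a median log2 ratio of 0.74, with 6 of 11 measured genes higher by at least 1.5-fold, 0 lower and 5 between, and its highest members were Il13, Areg, Il1rl1, the gene of the interleukin-33 receptor (1.40), and Il4. This median lay at percentile 100 of 10000 random lists matched on expression. It was under the 1.5-fold size with classes given equal weight and more than 1.5-fold higher without cluster 4. The same list had medians of 1.40, 1.59 and 0.70 in the NK-like, dendritic-like and fibroblast-like clusters of these libraries. Costimulation and activation genes had a median of 0.52 (7 of 15 higher, 3 lower, percentile 99.9), with the early response gene Egr3 at 1.89, the interleukin-2 receptor gene Il2ra at 1.42 and the costimulatory receptor gene Icos at 1.41, against Irf8 at -1.28. All genes at the minimum had a median of -0.12, with 498 of 8095 higher and 1362 lower. Scaling by TMM factors or by the median ratio of genes moved that median up by 0.24 and 0.26, so list medians are to be read against it.

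Interferon response genes were lower as a group. The type I interferon list had a median of -1.11, with 20 of 23 genes lower in Tc9, 0 higher and 3 between, and examples were the antiviral genes Ifit3 (-3.09), Rsad2 (-2.80) and Usp18 (-2.49). The interferon-gamma response list had a median of -0.61 (10 of 20 lower, 0 higher), with the GTPase genes Iigp1 at -1.61 and Irgm2 at -1.07, and class I antigen presentation had a median of -0.60 (7 of 13 lower, 0 higher), with H2-T22 at -1.25 and the immunoproteasome gene Psmb9 at -0.90. Markers of other cell types were lower beside them, with list medians of -4.57 for macrophages (7 of 7 genes), -3.62 for dendritic cells (3 of 3), -4.56 for natural killer cells (3 of 3), -8.24 for melanoma (5 of 5), -13.02 for red cells and platelets (4 of 4, with undetected genes at their bound) and -2.02 for CD8 T cells (3 of 4). With free RNA subtracted and low genes at the 3-count floor, these medians were -6.15, -6.85, -2.14, -1.97, -12.73 and -1.99 in that order. Macrophage and melanoma markers set the free RNA estimate, so their values follow partly by construction. With the expected free RNA of other cells subtracted, the type I interferon median was -1.06. It was more than 1.5-fold lower with the Cd4 UMI gate and closer to 0 with classes given equal weight. The gate takes barcodes of any cluster with Cd4 and Cd3 but no Cd8a or Cd8b1 UMIs. After thinning, Lyz2 was detected in 44.7% of its Tc1 and 1.10% of its Tc9 barcodes, against 27.4% and 0.828% in the CD4 clusters. In the NK-like, dendritic-like and fibroblast-like clusters the type I interferon median was -1.43, -2.18 and -1.23.

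Glycolysis genes had a median of -1.01 (12 of 16 lower, 0 higher), with the enzyme genes Tpi1 (-2.08) and Gapdh (-1.46) and the lactate exporter gene Slc16a3 (-1.68). The median was more than 1.5-fold lower with the Cd4 UMI gate. It was -0.88, -1.39 and -1.73 in the NK-like, dendritic-like and fibroblast-like clusters. Hypoxia genes had a median of -0.75 (8 of 13 lower, 1 higher), with Ddit4 at -1.92 and Bnip3 at -1.74. Cell cycle genes were lower in both phases, with medians of -0.86 for S (13 of 17 lower) and -0.94 for G2M (11 of 15 lower), and with Rrm2, which makes deoxynucleotides, at -1.63 and Aurkb, a mitotic kinase, at -2.14. Cholesterol and lipid genes had a median of -0.52 (7 of 15 lower, 2 higher), with the sterol synthesis genes Fdps at -2.09 and Idi1 at -2.08. Lyz2 (-4.83) and the other macrophage and red cell genes named above were lower in the same comparison.

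Cytotoxic genes had a median of -0.86 (7 of 12 lower, 0 higher), with Gzma (-2.64) and Gzmk (-1.87), while the CD8 markers Cd8a and Cd8b1 were lower beside them. Th1 genes had a median of -0.44 (8 of 19 lower, 3 higher), with the chemokine genes Ccl3 (-4.35), Ccl4 (-2.15, turning with classes given equal weight) and Ccl5 (-1.34). This median was 0.08 with the Cd4 UMI gate, which also takes barcodes outside the CD4 clusters. Naive, memory and stem-like genes had a median of -0.50 (7 of 15 lower, 0 higher), with Dapl1 (-4.44) and Lef1 (-1.10), and with classes given equal weight it was 0.02 and Dapl1 turned. The lists with medians near that of all genes were Treg core and effector (-0.07, 6 of 21 higher and 6 lower, with Il2ra up and the cytokine subunit gene Ebi3 down at -1.75), exhaustion and checkpoint (-0.01, with Nr4a1, an early gene of receptor signalling, at 1.51), Tfh (0.11), trafficking (-0.08), apoptosis and survival (-0.07) and nuclear oxidative phosphorylation (-0.22, 22 of 24 between), and the signs of all of these medians but Tfh turned under both other scalings, and that of Tfh without cluster 4. Th17 genes (0.50, 5 genes) had the transcription factor genes Rora at 1.39 and Ahr at 1.12 but Csf2 at -1.17, and their median turned with the Cd4 UMI gate and with classes given equal weight. With the expected free RNA subtracted, and low genes at the 3-count floor, the Th17 median was 1.16. Th9 genes (0.32, 5 genes) had the interleukin-9 receptor gene Il9r at 0.85 and Spi1, which is also a myeloid gene, at -3.94, and their median was -0.21 without the barcodes carrying the shared TRB chain and also turned without cluster 4.

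Signs of handling and RNA quality differed too. The dissociation stress list had a median of -0.28 (7 of 21 lower, 1 higher), which turned with classes given equal weight. Mitochondrial genes had a median of 0.27, with mt-Nd3 at 1.66, and ribosomal protein genes one of 0.05, with 72 of 85 between but the short genes Rpl38 (1.59), Rps29 (1.48), Rps28 (1.47) and Rps21 (1.44) higher. B or plasma, neutrophil, mast, fibroblast and gamma-delta T markers had 0 genes at the expression minimum in CD4 T cells, and endothelial markers had 1, so no median was taken.

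**Figure D2:**
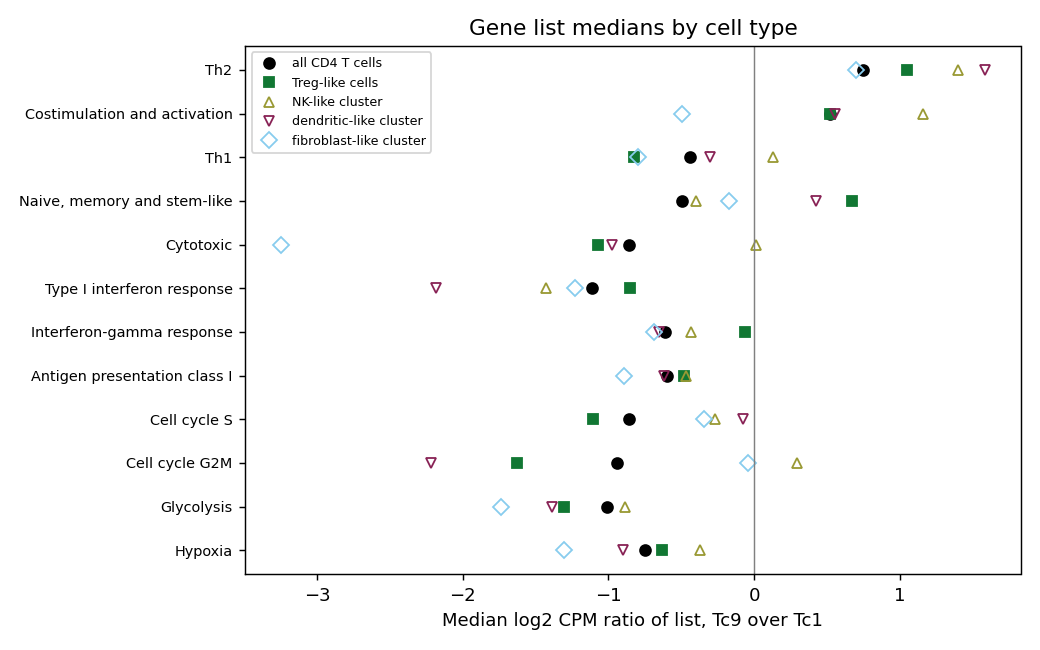
Median log2 ratio of CPM, Tc9 over Tc1 (horizontal axis), of 12 gene lists (vertical axis), with filled symbols for all CD4 T cells and for Treg-like cells and open symbols for clusters of 3 other cell types. Type I interferon, glycolysis and hypoxia medians lay below 0 in all 5 populations, and Th2 medians lay above 0 in all 5.

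The Treg-like class was the 1 class with at least 200 cells in both libraries. Without thinning, Cd8a was detected in 12.2% of its cells in Tc1 and 2.95% in Tc9, and 33 of its 575 TRB-bearing Tc9 cells carried the shared TRB chain. Treg-like cells of the Tc9 library had higher transcript levels of type 2 genes and lower ones of Th1, cytotoxic and cell cycle genes. Th2 genes had a median log2 ratio of 1.05 (6 of 9 higher, 0 lower), with Il1rl1, the interleukin-33 receptor of tissue regulatory T cells, at 82.2 and 378 CPM (2.20, 1.96 to 2.45), and Areg at 345 and 1209 CPM (1.81, 1.69 to 1.93). The list also counts Il4, detected in 1.14% of the Treg-like cells of Tc9 after thinning, against 2.17% of Tc9 barcodes outside the T lineage. Those barcodes include NK-like cells, so expression of Il4 by the class was not told apart from background. The Th2 median was no larger than the 1.40 of the NK-like and the 1.59 of the dendritic-like cluster. It was lower, though still above 1.5-fold, with the mean of each cell's CPM. Th1 genes had a median of -0.83 (12 of 18 lower, 4 higher), with Ccl3 at -4.69, Nkg7, a granule gene of cytotoxic cells, at -2.24 and Ccl5 at -2.10. Cytotoxic genes had a median of -1.07 (7 of 11 lower, 1 higher), with Gzmb at 790 and 376 CPM (-1.07, -1.16 to -0.98) and Prf1 at -2.56. This list's medians were 0.01 in the NK-like, -0.97 in the dendritic-like and -3.25 in the fibroblast-like cluster.

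Foxp3 itself was at 409 and 463 CPM in these cells, a log2 ratio of 0.18 (0.06 to 0.29), below the size counted. The Treg core and effector list split, with 7 of 21 genes higher, 7 lower and 7 between (median -0.15, turning under both other scalings), and with Lrrc32, which displays latent TGF-beta (1.62), and Il2ra (1.48) on one side and Ebi3 (-1.79) and the inhibitory receptor gene Tigit (-1.43) on the other. Pdcd1 was lower (-1.76), as was Cd160 (-2.47) among exhaustion genes, though it turned with a mitochondrial share of at most 5%, while Nr4a1 was higher (1.46). Naive, memory and stem-like genes were higher in this class (median 0.67, 8 of 14 higher, 2 lower), with the tissue exit receptor gene S1pr1 at 1.71, Bach2 at 1.44, Klf2 at 1.27 and Tcf7 at 0.73. Costimulation genes had a median of 0.52, with Cd40lg at 1.83. After thinning, Cd40lg was detected in 3.49% (Tc1) and 10.5% (Tc9) of the Treg-like cells, against 3.26% and 9.24% of barcodes outside the T lineage. Tcf7 was detected in 7.36% and 11.1%, against 9.50% and 14.4%. Those barcodes include NK-like cells and are not a pure measure of background. The comparison thus cannot tell expression by the class itself from background for either gene. The 5 highest genes were the cholesterol exporter gene Abcg1 (2.93), Gm11290 (2.92), Tnfsf8, the gene of CD30 ligand (2.61), the activin receptor gene Acvr2a (2.38) and Trat1 (2.33).

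Type I interferon genes were lower in the Treg-like cells of Tc9 (median -0.85, 16 of 21 lower, 0 higher), with Usp18 at -1.78 and Irf7 at -1.75, whereas the interferon-gamma list gave -0.06 (6 of 20 lower, 3 higher) and turned under both other scalings. Glycolysis genes had a median of -1.31 (12 of 16 lower), with Gapdh at -1.74, and cholesterol and lipid genes one of -0.86 (10 of 15 lower), with Sqle, a sterol synthesis gene, at -2.44. The cell cycle medians were -1.11 for S and -1.63 for G2M, with Birc5, which protects dividing cells, at -3.33. The Foxp3-rich cycling cluster 12.6 is not part of this class. The 5 lowest genes were 4 haemoglobin genes and Lyz2, and under the added rule, which leaves out haemoglobin genes and genes with much expected free RNA, they were Ccl3, Hspa1a (-3.64), the replication gene Pclaf (-3.54), Hspa1b (-2.98) and Nrn1 (-2.52). Macrophage markers were lower in this class as well (median -4.46, 7 of 7), as were red cell and platelet markers (-10.10, 4 of 4) and Cd8a (-2.50). In the other CD4 T cells the Th2 median was 1.02 (8 of 11 higher) and the type I interferon median -1.34 (22 of 24 lower).

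The TCR libraries addressed how far the infiltrating CD4 T cells belonged to expanded clones. Of CD4 T cells with 1 TRA and 1 TRB chain, 41.8% (358 of 856, 38.5 to 45.2%) in Tc1 and 61.4% (1050 of 1710, 59.0 to 63.7%) in Tc9 belonged to clonotypes of at least 3 cells, a difference of 19.6 percentage points (15.5 to 23.6). Drawn to 856 cells, the Tc9 share was 53.4% (range of 100 draws 49.2 to 57.0%), so that the difference was 11.6 points at equal numbers of cells. Naive-like cells, 0 of them expanded, made up 186 of the 856 Tc1 pairs and 6 of the 1710 Tc9 pairs. The differences here were not recomputed without them and so include the effect of that unequal share. These differences therefore do not show more expansion in Tc9 among the other CD4 T cells. Clonotypes numbered 516 in Tc1 and, at equal numbers, 414 in Tc9 (391 to 440). The Shannon index, which is higher in more diverse repertoires, was 5.64 in Tc1 and 5.38 (5.31 to 5.50) in Tc9 at equal numbers, while the Simpson indices were 0.988 and 0.989. Pairs came from 856 of 2410 CD4 T cells in Tc1 and 1710 of 7313 in Tc9, and 1713 of the Tc9 cells had a TRB chain only. Without cluster 4 the difference in expanded share was 49.3 points.

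Expanded clones lay mainly outside the regulatory class in Tc9, and in Tc1 most of the expanded cells outside it were in cluster 4. Among Treg-like cells, 17.1% (20 of 117, 10.8 to 25.2%) in Tc1 and 13.7% (43 of 315, 10.1 to 17.9%) in Tc9 were in expanded clonotypes, with overlapping intervals. Outside the Treg-like class the shares were 45.7% (42.1 to 49.4%) and 72.2% (69.8 to 74.5%), so that the gap between the outside and the Treg-like cells was 28.6 points in Tc1 (19.8 to 36.0) and 58.5 points in Tc9 (53.6 to 62.8). Cluster 4 held 266 of the 338 expanded Tc1 cells outside the Treg-like class. With its cells left out, 18.9% (72 of 380, 15.1 to 23.3%) of the others were in expanded clonotypes, with an interval overlapping that of the Treg-like cells. These 380 include the 186 naive-like cells, 0 of them expanded. The lower share thus does not show that the Tc1 gap rested on cluster 4 alone. The Tc1 gap turned when cluster 4 was removed before clonotypes were counted, an alternative chosen after seeing the data. The naive-like cells stayed in that alternative too. Th2-like cells were expanded in 66.7% (12 of 18) and 86.3% (196 of 227), Th1 effector-like cells in 25.9% and 59.1%, and cluster 4 of Tc1 in 74.1% (266 of 359). These class shares were not matched for the number of pairs, and with Tc9 drawn to 856 cells, also added after seeing the data, its shares were 7.14 to 17.6% for Treg-like cells (range of 100 draws) and, as means, 62.8% outside that class, 78.3% for Th2-like and 48.2% for Th1 effector-like cells. None of the 186 naive-like cells of Tc1 was in an expanded clonotype, with an exact upper bound of 1.96%. They are counted in the Tc1 shares outside the Treg-like class and lower them, so the difference from Tc9 there also includes their unequal number.

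**Figure D3:**
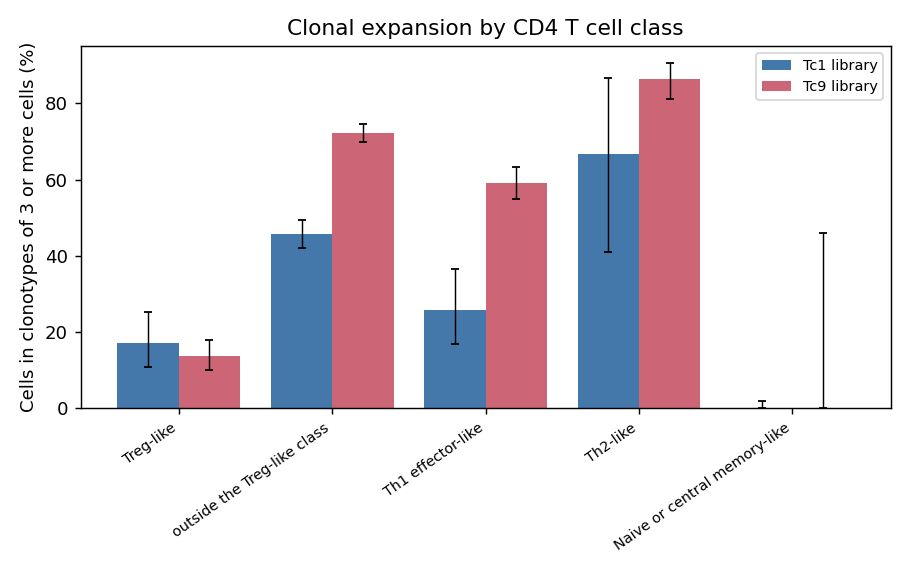
Share of CD4 T cells with 1 TRA and 1 TRB chain (percent, vertical axis) that belonged to clonotypes of at least 3 cells, by class and library, with exact 95% binomial intervals. The Treg-like shares were 17.1% and 13.7%, and the shares outside that class were 45.7% in Tc1 and 72.2% in Tc9, without matching for the number of pairs. Naive-like cells, unequal in number between the libraries, are counted outside that class.

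The largest Tc1 clonotype, TRAV6-7-DV9 and TRAJ48 with the CDR3 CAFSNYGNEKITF paired with TRBV3 and TRBJ1-1 with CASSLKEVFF, held 57 cells (6.66%, 5.08 to 8.54%), and the 4 that followed, among them 1 with TRBV16 and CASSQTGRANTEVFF and another TRBV3 one with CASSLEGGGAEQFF, held 49, 25, 20 and 14 cells, of which 149 of the 165 cells of all 5 were in unnamed clusters. The largest Tc9 clonotype, TRAV7D-2 and TRAJ22 with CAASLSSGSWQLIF paired with TRBV31 and TRBJ2-4 with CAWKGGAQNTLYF, held 90 cells (5.26%, 4.25 to 6.43%), 25 of them Th2-like and 12 Th1 effector-like. The 4 next Tc9 clonotypes held 86, 68, 41 and 37 cells, and Th2-like cells were found in all 5 of these and in 4 of the 5 largest Tc1 clonotypes. By TRB gene, TRBV14 was used by 0.364% of the Tc1 and 8.66% of the Tc9 CD4 T cells with a single TRB chain, TRBV3 by 17.8% and 10.1%, the ambiguous pair TRBV12-2 or TRBV13-2 by 7.71% and 13.4%, TRBV13-1 by 9.53% and 4.95%, and TRBV31 by 6.91% and 10.8%. Counted once per clonotype, TRBV14 made up 0.543% and 1.85% and TRBV3 9.65% and 11.5% of clonotypes.

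No clonotype of the CD4 T cells was found in both libraries, whether by nucleotide pair (516 and 689 clonotypes), by amino acid pair or by TRB chain alone. Over all barcodes of the TCR libraries, 1 nucleotide pair was shared, among 1356 and 704 clonotypes. It was TRAV7N-5 and TRAJ40 with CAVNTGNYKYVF paired with TRBV14 and TRBJ1-6 with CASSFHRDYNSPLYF, on 42 barcodes of Tc1 and 155 of Tc9, and its TRB chain alone was on 59 and 487. This receptor was the third largest clonotype among the Tc9 CD4 T cells, with 68 cells, though its TRB chain was in clusters where Cd4 was detected in 19.4% of the carriers (14.5 to 25.1%) against 70.3% (68.8 to 71.9%) of cells with another TRB chain. It accounted for 232 of the 303 Tc9 CD4 T cells with TRBV14. Cd8a or Cd8b1 was detected in 38.8% of these 232 carriers and in 4.34% of the other cells.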

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

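The tests on free receptor RNA and on Cd4 UMIs in the carriers were chosen only after the result was seen, and so was the use of the Cd4 share to weigh doublets. Signals appeared outside the CD4 T cells that the comparisons used. The sorted libraries held 2281 CD8 or other T cells in Tc1 and 460 in Tc9, and 7242 barcodes outside the T lineage in Tc1. A single receptor pair was found in both libraries, on 42 barcodes in Tc1 and 155 in Tc9, although the mice of the libraries differed. In cluster 13, a T cell cluster with Cd8a or Cd8b1 in 80.2% of its Tc9 barcodes, a Y-linked gene was detected in 28.9% of the Tc9 barcodes (24.7 to 33.4%), while it was detected in 0 of 2410 CD4 T cells of Tc1, which allows a share of up to 0.124%. These groups are unlike. In the CD4 T cells of Tc9 the share was 1.41% (103 of 7313). Among Tc1 barcodes with the shared TRB chain in CD8 or other T clusters, 1 of 47 had a Y-linked UMI.

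The receptor found in both libraries sat on 232 barcodes inside the Tc9 CD4 T cell clusters, taken with any number of TRB chains, and 0 of them had a second TRB chain. Free receptor RNA was argued against, because its TRB contig held 4.5 times the UMIs of the library's median TRB contig in these barcodes. Doublets of a CD8 and a CD4 T cell were argued against by the Cd4 share, 19.4% against 70.3% in the other cells of these clusters, while the test set beforehand, median UMIs at 1.17 times those of other cells (1.08 to 1.26), did not decide alone. T cells with this receptor that cluster with CD4 T cells are what the 19.4% suggests, and a candidate explanation is transferred Pmel-1 cells, whose known receptor uses TRBV14, that passed the CD4 sort. Y-linked genes in 16.8% of these carriers and in 1 of 3479 other cells set them apart from the host cells in Tc9 but not in Tc1 (1 of 59 carriers), and the Thy1.1 mark was not analysed here, so this remains a hypothesis.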

How the results depend on the processing

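Tests without cluster 4, without the naive-like class, without the top Scrublet scores, without the shared receptor and with free RNA subtracted were chosen only after the result was seen. The 19 main results were recomputed 157 times in all, of which 77 stayed within their counting error, 75 moved beyond it in the same direction and 5 turned. A value counted as turned when its sign changed and the reported difference excluded 0 (shares) or was at least 1.5-fold (medians and genes), so that sign changes of smaller medians count as moved. Of 533 recomputed list medians other than these, 305 stayed and 228 moved, and of 2292 values of named genes 1486 stayed, 798 moved and 8 turned. Without the shared receptor, by amino acid pair, with clonotypes of at least 2 or 10 cells called expanded, with contigs of at least 3 UMIs and with thinning to 1000 UMIs, every main result that could be recomputed stayed. Removal of the shared receptor reaches only barcodes with a recovered receptor, and 53.2% of the Tc9 CD4 T cells had any. A Y-linked gene was detected in 103 of the 7313 Tc9 CD4 T cells, and 39 of these were carriers. Among cells with another TRB chain 1 of 3479 had one, so the others lay in cells without a recovered TRB chain. Cells with a Y-linked transcript thus remained after the removal, which makes it a partial check only. Without barcodes with the shared receptor the values of Il13 and the Th9 list also moved.

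Shares are differences Tc9 minus Tc1 in percentage points: share of each CD4 T cell class: Treg-like, share of each CD4 T cell class: Th2-like, share of each CD4 T cell class: Naive or central memory-like, share of each CD4 T cell class: Th1 effector-like, share of each CD4 T cell class: Interferon-response-like, share of each CD4 T cell class: Cycling-like, and share of CD4 T cells with a Foxp3 UMI. List medians are log2 ratios, in all CD4 T cells unless Treg-like cells are named (log2 CPM ratio in all CD4 T cells: Th2 list median, log2 CPM ratio in all CD4 T cells: Glycolysis list median, log2 CPM ratio in all CD4 T cells: Type I interferon response list median, log2 CPM ratio within each class: Treg-like: Type I interferon response list median, and so on). The cause was not tested except where a sentence gives it. Without cluster 4 the Treg-like share (-3.87) and the Foxp3 UMI share (-3.48) turned, while Th2-like (8.34), naive-like (-34.6), Th1 effector-like (13.4), interferon-response-like (-6.68) and cycling-like (-1.94) shares, the Th2 (1.45), type I interferon (-1.40) and glycolysis (-0.92) medians and the expanded share (49.3) moved. Part of this follows by construction, since 1121 of the cells removed were from Tc1. Without the naive-like class, the Treg-like (3.45), Th1 effector-like (18.5) and interferon-response-like (-4.08) shares moved, by construction of the smaller Tc1 total. At resolution 0.6 the Th2-like difference was 8.81, naive-like -12.5, interferon-response-like -51.8 and cycling-like -2.28. There the interferon-response-like name covered at least 51.8% of the Tc1 CD4 T cells, against 4.07% in the main clustering. Its value at that resolution thus concerns a different set of cells. At resolution 1.5, Th2-like was 12.2, naive-like -22.9, Th1 effector-like 22.5 and interferon-response-like -1.90. With components centred per library the interferon-response-like share turned (0.205), and Treg-like was 10.2, Th2-like 8.68, naive-like -21.2, Th1 effector-like 18.5 and cycling-like -1.66. With at least 1000 genes the Th1 effector-like share turned (-0.204), and Th2-like was 11.8 and naive-like -20.0. With a mitochondrial share of at most 5%, Th2-like was 12.96, Th1 effector-like 24.4, interferon-response-like -1.86 and the type I interferon median -1.03, and in Treg-like cells Cd160 (0.57) and Klrd1 (0.50) turned. Thinned to 2000 UMIs before clustering, Treg-like was 0.766, Th2-like 28.9 and interferon-response-like -0.756. Without barcodes with 2 TRB chains, Th2-like was 27.9, naive-like -15.1 and interferon-response-like -1.92. Without the top Scrublet scores, Th2-like was 19.0, the type I interferon median -1.06 and the Treg-like Th2 median 0.80. A Th2-like difference of 19.0 or more means that the name covered more of the Tc9 CD4 T cells than the 12.4% of the main clustering. Those Th2-like values thus concern different sets of cells. Some of these clusterings gave no cluster with the name of a class, and that share then has no value. Not thinned, the Foxp3 share difference was 4.79, by construction at the deeper Tc9 cells. With TMM factors the medians were 0.99 for Th2, -0.87 for type I interferon and -0.77 for glycolysis, and in Treg-like cells -0.69 for type I interferon and -1.14 for glycolysis. With the median ratio of genes they were 1.001, -0.86 and -0.75, and in Treg-like cells -0.69 and -1.14. Both scalings add a constant by construction. With the mean of each cell's CPM, type I interferon was -1.28, and in Treg-like cells Th2 was 0.63 and glycolysis -1.15. With no filter on low values type I interferon was -1.68, and -1.26 in Treg-like cells, with more genes by construction. With free RNA subtracted, type I interferon was -1.06, glycolysis -0.90 and Th2 in Treg-like cells 0.84 where genes under 3 counts after subtraction were left out (1.04 with them at the floor), and Ier3 turned (0.29). With classes weighted equally, Th2 was 0.47, type I interferon -0.75 and glycolysis -0.83, and Hspa1a (0.16), Hspa1b (0.29), Ccl4 (0.96), Dapl1 (0.018) and Hsph1 (0.59) turned. Without cycling cells glycolysis was -0.97. With the Cd4 UMI gate, which takes barcodes of any cluster, Th2 was 0.86, type I interferon -1.80 and glycolysis -1.68.

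By TRB chain only, the difference in the share of cells in expanded clonotypes was 27.5, in clonotype diversity: Shannon index at equal numbers of cells -0.508, and in clonotype diversity: number of clonotypes at equal numbers of cells -230.7. Over all receptor barcodes these were 8.97, -0.159 and -209.1, and the shared clonotypes numbered 1. At equal numbers of cells the expanded share difference was 11.6, which follows from the larger number of Tc9 pairs. Without cluster 4 the value of expanded share and class of the clonotypes: outside minus inside the Treg-like class, Tc1 turned to -7.09, as cluster 4 held most expanded Tc1 cells outside that class. The naive-like cells, none of them expanded, were still counted outside that class there. At equal numbers of cells, a comparison added after seeing the data, expanded share and class of the clonotypes: outside minus inside the Treg-like class, Tc9 moved to 50.8.

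No paired analysis was possible because each group had 1 library from 1 pool. The small classes rest on few cells, with 53 Th2-like and 38 cycling-like cells in Tc1.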

Other observations

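The test of the type I interferon shift against free RNA and the one within the Treg-like class were chosen only after the result was seen, as was every comparison of the receptor carriers. The barcodes with the TRB chain found in both libraries, 59 in Tc1 and 486 in Tc9, differed in the cytokine transcripts detected in them. At least 1 of Il4, Il5 and Il13 was detected in 27.0% (23.1 to 31.1%) of the Tc9 carriers and in 0 of 59 in Tc1, which allows a share of up to 5.08%, while in barcodes outside the T lineage, also not thinned, it was detected in 7.19% in Tc9 and 2.44% in Tc1. The median depths of the carriers were 7818 UMIs in Tc9 and 15328 in Tc1. Il13 was at least 133-fold higher in the Tc9 carriers, Areg had 3 and 2286 UMIs (log2 ratio 7.51, 5.96 to 9.79), Il10 had 1 and 386 UMIs (6.53, 4.04 to 11.83), and Gata3 stood at 34.7 and 293 CPM (3.08). Ifng (-3.15), Gzma (-2.39), Gzmb (-1.88) and Prf1 (-3.04) were lower in them. Th2 genes had a median of 4.15 (10 of 11 higher), Treg core and effector genes 1.56 (14 of 20 higher) and cytotoxic genes -2.02 (11 of 15 lower). Cell cycle genes were lower too (-1.64 for S and -2.54 for G2M), with 37 of the Tc1 carriers in cluster 12, which was cycling-like but for its parts 12.5 and 12.9, and 242 of the Tc9 ones in cluster 13. In those cluster 13 carriers Cd8a or Cd8b1 was detected in 83.9%, Cd4 in 23.1% and Foxp3 in 24.8%. The doublet tests covered only carriers in CD4 clusters. Macrophage markers (-5.70) were lower in the Tc9 carriers as well, and gamma-delta T markers were higher (1.72, 3 of 4 genes). State, cycle, doublets with other T cells, free RNA and library were thus not separated. Il9 was found in 1 kept barcode, a Tc9 carrier with 30 UMIs, and in 0 of 11933 barcodes of Tc1.

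Of the expanded clonotypes with a Th2-like cell, 43 of 45 in Tc9 also had Th1 effector-like or cluster 0 cells, against 72.2 of 73 when class names were shuffled, and 6 of 11 in Tc1, against 5.63 of 9.08. This count leaves out cluster 4, which held 266 of the 358 expanded Tc1 cells, so the libraries are not alike in it. Of those with a Treg-like cell, 15 of 17 in Tc9 also had Th1 effector-like, Th2-like, cluster 0 or cluster 4 cells, against 29.1 of 29.1, and 2 of 6 in Tc1, against 13.6 of 13.6. Other cell types of the same libraries shared several of the list differences. Th2 medians were 1.40 in the NK-like, 1.59 in the dendritic-like and 0.70 in the fibroblast-like cluster, and glycolysis medians were -0.88, -1.39 and -1.73. Free RNA of the many Tc9 CD4 T cells was not subtracted in these clusters.

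Type I interferon genes were lower in the Tc9 CD4 T cells. Free RNA of other cells in the Tc1 library, as estimated, was argued against, since it came to 6.81% of the Tc1 level of the median list member. The estimate covers only RNA with the profile of the barcodes outside the T lineage. It left the red cell and platelet median at -12.73, against -13.02 before subtraction, so other free RNA was not weighed. Different shares of the CD4 T cell classes were argued against as the whole cause by the median of -0.85 within the Treg-like class. A shift shared by other cell types of the library was found, since the highest median over the NK-like, dendritic-like and fibroblast-like clusters was -1.23. This may reflect the tumour milieu of each group or the handling of each library, which 1 library per group leaves open.

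The 4 short ribosomal protein genes Rpl38, Rps29, Rps28 and Rps21 were higher in the Tc9 CD4 T cells, with a median of 1.48. A shift shared by other cell types of the library was found here as well, as the lowest median over the same clusters was 1.35. A difference in library preparation may underlie this, but gene length was not tested and a shared response of all cell types stays open.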
